A study of Mus musculus with 6 samples.

How the data were processed

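Total RNA from mouse brain synaptosomes was measured on 6 one-colour Agilent microarrays, 3 of the knock-in group and 3 of the wild-type group. Synaptosomes are pinched-off nerve terminals, with attached postsynaptic membrane, that are isolated from homogenised brain. Per the labels, RNA was labelled with Cy3 by a low-input amplification kit, every sample had an RNA integrity number of 10, and 0.2 µg of RNA entered the labelling of 5 samples, while the amount for knock-in replicate 1 is given as 0.0 µg. The labels do not say whether the samples came from separate animals, so the p-values measure the spread between these samples, which may be technical.

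Per the file headers, the spots were read with Agilent Feature Extraction 10.7.3.1, which deposited for each spot an intensity on a linear scale: the raw mean and median brightness, the median local background, and a processed intensity that is background-subtracted and detrended within the array. Each array had 62976 spots, of which 59305 were not controls and held 55681 different probes. The processed intensities were not normalized between arrays, per the file headers. The authors also deposited a value table in log2 units. Ranked over spots, each of its columns had a Spearman correlation of 1.0000 with the raw median intensity of its own array, and the medians of its columns lay between 6.55 and 6.56, so its scale and direction are known from the values, while how its columns were brought to a common distribution is not given in the sources used here.

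The analysis started from the processed intensity. Control spots were left out, and saturated spots were kept. Spots marked as outliers were left out, except where every spot of a probe was so marked on an array. Log2 values were scaled by subtracting the 75th percentile of each array over its non-control spots, those marked as outliers included. Spots of one probe were averaged on the log2 scale. A probe was kept when it was well above background on at least 3 of the 6 arrays, which left 29318 probes, and a gene was represented by its brightest kept probe, chosen over all arrays without regard to group, which gave 20975 genes. Probes were named through the RefSeq table of assembly GRCm38.p6, used for names only: 27235 probes were named by their accession, 3581 by a current symbol and 565 by a unique older symbol, 24300 kept the name in the file, and 3403 names differed from those in the file. Coordinates are those of the array annotation on mouse build mm9.

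Groups were compared with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, two-sided), with Benjamini-Hochberg adjustment over genes and a threshold of 0.05. Differences are knock-in minus wild type on the log2 scale, with the moderated standard error (SE). The median difference over all genes was -0.05, so a list mean near that value is no shift. Fixed gene lists were tested with limma's camera at a preset inter-gene correlation of 0.01, adjusted over the 30 lists with at least 4 measured members, and again with camera at an estimated correlation and with fry. The SE between arrays of a list mean is that of the group term in an unweighted linear fit of the list mean of each array. For single values an exact two-sided permutation test over the 6 arrays was used, whose smallest possible p with 3 against 3 is 0.1. Where all probes of a gene were not well above background on every array of a group, the fold is a bound, taken against the higher of the probe's own value and the lowest value among probes well above background on each array of that group. Such a bound holds for the main processing only.

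The genes named were fixed by a rule before the data were examined: Fmr1, the 10 genes of each direction with the largest differences among those past the threshold and without overlap between groups, filled to 10 with the non-overlapping genes of smallest unadjusted p, and up to 4 members of smallest p of each list. Placeholder names are counted and not named by that rule. The gene lists, among them markers of other brain regions and cell types, and the alternatives were also fixed before the data were examined, except where stated.

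The 4 arrays of slide 1 held the 3 knock-in samples and wild-type replicate 3, and the 2 arrays of slide 2 held wild-type replicates 1 and 2. Slide was therefore tried as a fixed block, as a random block (consensus correlation -0.02) and by using slide 1 alone. With slide 2 holding wild-type arrays only, the fixed block and slide 1 alone give the same differences. Both compare the knock-in arrays with wild-type replicate 3 alone, so list p-values under the block rest on 1 wild-type array. The other alternatives were normexp background correction of the raw mean intensity with an offset of 50, quantile and cyclic loess normalization, scaling by the median of detected probes, no filter and a stricter filter on dim probes, the mean of all probes of a gene, every probe on its own, an intensity trend with robust moderation, array weights, a replicate block, the authors' value table, and leaving out each array in turn.

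The fit was tested on simulated data: intensities for the 20975 genes were drawn from the observed means and spreads for this comparison, with 100 genes changed by 1 and 100 by 2 on the log2 scale. At the threshold 56 of the genes changed by 1 and 91 of those changed by 2 were recovered, with 10 false calls. With no change simulated, 0 genes were called and 5.14% had an unadjusted p under 0.05. In the same simulated data a list of 30 genes moved by 0.5 was found by camera, and 7 of 200 random lists had p under 0.05. Genes were simulated independently of each other, whereas members of the lists tested below had estimated correlations of up to 0.95. The simulation therefore does not show how camera at the preset correlation behaves for lists of correlated genes.

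The precision is limited by the number of arrays. A planned comparison of genes with and without seed matches to the 3 microRNAs named in the series title was not run, because no transcript sequences were used here.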

Results

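Brain synaptosome RNA was profiled in knock-in and wild-type mice, 3 samples each, on one array per sample. The title of the series concerns the regulation of the FMR1 transcript by miR-101, miR-129-5p and miR-221 and the fragile X-associated tremor/ataxia syndrome, a late-onset disorder of carriers of a moderately expanded CGG repeat in FMR1. The comparison therefore asks which synaptosomal transcripts differ between knock-in and wild type. The genotype field of the 3 knock-in samples reads knock-out, whereas their sample names and the series design read knock-in; they are called knock-in here. Processed signals at the 75th percentile were 883, 909 and 910 for the knock-in arrays, 823 for wild-type replicate 3 on the same slide, and 578 and 580 for wild-type replicates 1 and 2 on the other slide. Between 52.9% and 55.7% of non-control spots were well above background, and 0 were saturated. Correlations between arrays across genes, which are not independent replicates, lay between 0.981 and 0.994.

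Fmr1, which encodes the RNA-binding protein FMRP, had a higher signal in all 3 knock-in arrays than in any wild-type array, by each of its 3 probes. The brightest probe lies on chromosome X at 65970891 to 65970950 of build mm9 and starts at base 4147 of the transcript. It read 2.19 ± 0.10 in knock-in and 1.37 ± 0.05 in wild type (log2 relative to the 75th percentile, SD, n = 3 each), a 1.77-fold difference. The log2 difference was 0.82 (SE 0.10), with limma's adjusted p = 0.198 over 20975 genes and an exact permutation p of 0.1, the smallest that 3 against 3 arrays allow. The 2 dimmer probes, at 65948200 to 65948259 and 65948720 to 65948779, start at bases 471 and 588 and differed by 0.39 and 0.45, or 1.31-fold and 1.37-fold. Within each array, the probe near the end of the transcript minus the mean of the other 2 was higher by 0.40 in knock-in, again without overlap between groups (exact permutation p = 0.1). With slide as a block, which here compares the knock-in arrays with the wild-type array of their own slide, the Fmr1 difference was 0.83 with adjusted p = 0.549.

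**Figure D1:**
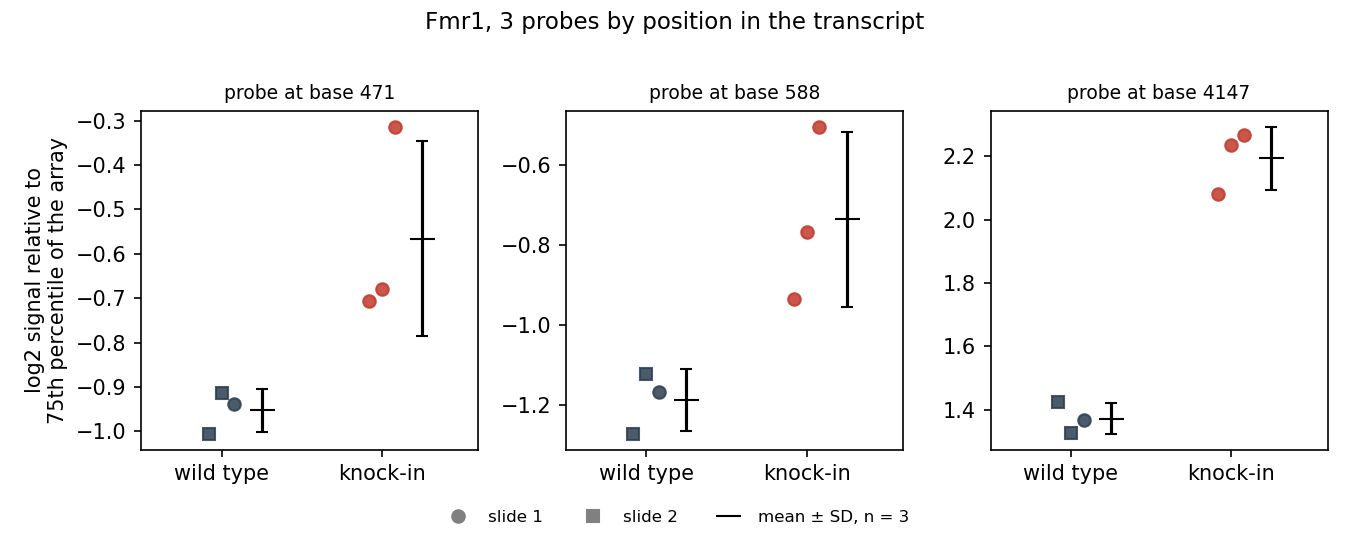
Fmr1 signal on each array (log2 relative to the array's 75th percentile), one panel per probe in order of position in the transcript (bases 471, 588 and 4147). Circles are slide 1, squares slide 2, and bars the mean ± SD (n = 3); on each probe all 3 knock-in arrays lie above all wild-type arrays, by 0.39, 0.45 and 0.82 on average.

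Across the transcriptome, 2 of 20975 genes passed limma's adjusted p of 0.05, both higher in knock-in. Both carry placeholder names and were named after their values were seen: the transcript ENSMUST00000065741, measured on chromosome 7 at 106928544 to 106928603, and a long intergenic transcript measured on chromosome 3 at 58124895 to 58124954. Neither was well above background on any wild-type array, so in the main processing knock-in exceeded wild type at least 3.82-fold and at least 4.31-fold, with limma's adjusted p = 0.0153 for each. The log2 differences as measured, with wild type near background, were 3.51 (SE 0.20) and 4.23 (SE 0.25). They stayed about as large with slide as a block, at 3.47 (SE 0.30) and 4.39 (SE 0.38). Both then missed the threshold (adjusted p = 0.0844) as the standard errors grew, since the knock-in arrays are compared with 1 wild-type array, and 7 other genes passed. In all, 13 and 12 of 21 alternatives lost the 2 calls. The size also changed with the processing. With normexp the differences were 0.74 and 1.18 (adjusted p = 0.227 for each), below the bounds of 1.93 and 2.11 in log2. With the authors' value table they were 1.95 and 2.36 (adjusted p = 0.0583 and 0.114). At an unadjusted p under 0.05 there were 934 genes higher and 1342 lower in knock-in, 2276 in all where 1049 would be expected with no effect. The 3 knock-in arrays lay wholly above or below the 3 wild-type arrays for 4262 genes, or 20.3%, where chance gives 10%. Both expectations are averages, from which a single split of the arrays can lie far. Setting knock-in replicates 1 and 2 and wild-type replicate 1 against the rest gave 2330 genes at an unadjusted p under 0.05. The other splits that mix the groups gave fewer than the real one, between 241 and 1768. The excess over 1049 can therefore not be assigned to genotype.

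None of the following genes passed the threshold; they are those of smallest unadjusted p whose arrays did not overlap. On the higher side, Sult2a7, a sulfotransferase of a family with similar members, was well above background on the 3 knock-in arrays and on 0 wild-type arrays, at least 4.86-fold higher (adjusted p = 0.0518). Tcim, a regulator of Wnt signalling, likewise was at least 2.81-fold higher (adjusted p = 0.120). Utp14b, a ribosomal RNA processing factor, differed by 1.35 (SE 0.14), and it was well above background on 2 of the 3 wild-type arrays. Apaf1, the scaffold of the apoptosome, differed by 1.15 (SE 0.16), the interferon-inducible Ifi204 by 1.00 (SE 0.14), and Alkal2, a ligand of the ALK receptor, by 0.88 (SE 0.11). The germ-cell RNA-binding factor Dnd1 differed by 0.69, the integrin Itgax by 0.60 and Hspa5, the main chaperone of the endoplasmic reticulum, by 0.57 (SE 0.09). Background correction by normexp turned the sign for Itgax, to -0.076.

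On the lower side, Mcts1, a translation re-initiation factor on chromosome X, read 0.506 of wild type (log2 difference -0.98, SE 0.10, adjusted p = 0.120). Fem1al differed by -0.89 (SE 0.10), the ceramide synthase gene Cers3 by -1.03 (SE 0.12), and Ankrd34c read 0.499 of wild type. The antisense transcript Atad3aos was well above background on 0 knock-in arrays and at least 2.54-fold lower there. Rasl12, a Ras-like protein, differed by -1.62 (SE 0.28), the histone demethylase Kdm4d by -0.81, Aurkaip1, a protein of the mitochondrial ribosome, by -0.66, Mesp2 by -0.64 and Arhgap4 by -0.54. Both kept probes of Aurkaip1 and both of Arhgap4 had the same sign. Cross-hybridisation among members of gene families, such as those of Sult2a7 and Ifi204, was not tested.

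Activity-regulated genes, the transcripts that neuronal firing induces within minutes to hours, were higher in knock-in as a list. Of 29 measured members 25 were higher and 4 lower, with a mean log2 difference of 0.51 (1.43-fold) and adjusted p = 2.26e-09 by camera. The exact permutation p of the list mean was 0.1, the smallest possible. With an estimated correlation between members the adjusted p was 0.881. Arc, which acts in synaptic plasticity, read 2.23-fold of wild type (log2 difference 1.16, SE 0.28), Fosb 1.97-fold, Klf4 2.08-fold and Egr4 1.72-fold. In each of these genes, 3 of 3 knock-in arrays lay above all wild-type arrays, as for 11 members in all, while 3 members, named after their values were seen, lay wholly below: Homer1 (-0.44), Egr3 (-0.33) and Rheb (-0.18). Of the kept probes, 4 of 5 of Homer1 and 1 of 3 of Rheb were lower. Over all genes 0 members passed limma's threshold, and 5 passed when adjusted over the list alone; 15 higher and 2 lower members had an unadjusted p under 0.05. The list mean on single arrays, relative to the mean of all 6, was 0.39, 0.41 and -0.03 in knock-in replicates 1 to 3 and -0.14, -0.07 and -0.56 in the wild-type ones. With slide as a block, which compares the knock-in arrays with wild-type replicate 3 alone, the mean difference was 0.81 (95% interval 0.05 to 1.58). That array had the lowest list mean of the 6.

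Genes of the respiratory chain and ATP synthase encoded in the nucleus were lower in knock-in by a small amount: 68 of 72 members were lower, with a mean log2 difference of -0.14 against a median of -0.05 over all genes (camera, adjusted p = 1.53e-04). The adjusted p was 0.903 with an estimated correlation. The ATP synthase alpha subunit gene Atp5a1 differed by -0.32 (SE 0.10), Cox7a2 by -0.35, Ndufc1 by -0.26 and Ndufb4 by -0.27, each without overlap, and 0 members passed when adjusted over the list alone. Wild-type replicate 2 carried much of the difference: relative to the mean of all 6 arrays it read 0.20, and without it the list mean was -0.073 (adjusted p = 0.0084). The call was lost with slide as a block (mean -0.07, SE between arrays 0.10 against 0.07 without the block, adjusted p = 0.0884), with quantile normalization (-0.05, 0.201), with normexp (-0.10, 0.194) and with the authors' value table (-0.03, 0.428).

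Heat shock, unfolded protein response and proteasome genes were higher as a list, with 21 of 37 members higher, a mean of 0.10 and adjusted p = 0.0086 by camera (adjusted p = 0.881 with an estimated correlation). The members of smallest p were Hspa5 at 1.48-fold, the co-chaperone Bag3 at 1.52-fold (log2 difference 0.60, SE 0.11), the small heat shock protein Hspb8 at 1.32-fold and the stress-induced transcription factor Ddit3 at 1.30-fold, while Hspa8, singled out after its value was seen, lay wholly below wild type at 0.801 by its brightest probe, although another of its 3 probes was higher by 0.52. Over all genes 0 of the list passed, and 2 passed when adjusted over the list alone. With slide as a block the mean was 0.10 (adjusted p = 0.0240), and without knock-in and wild-type replicate 1, chosen after seeing the data, it was 0.075 and missed the threshold (adjusted p = 0.101).

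**Figure D2:**
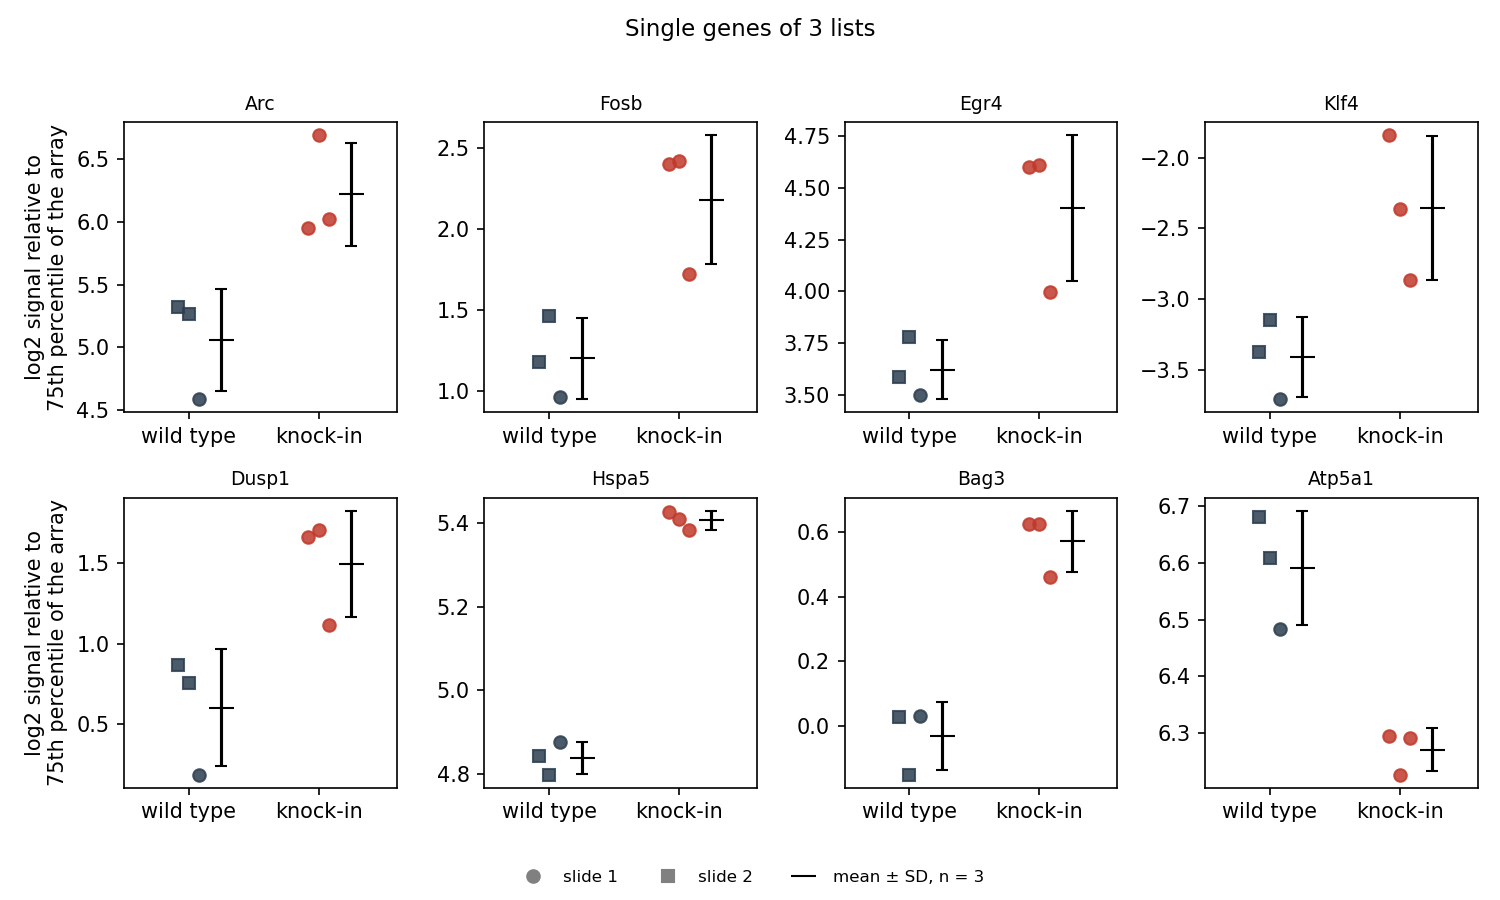
Signal of single genes on each array (log2 relative to the array's 75th percentile): Arc, Fosb, Egr4, Klf4 and Dusp1 of the activity-regulated list, Hspa5 and Bag3 of the heat shock list, and Atp5a1 of the respiratory chain list. Circles are slide 1, squares slide 2, and bars the mean ± SD (n = 3); the 3 knock-in arrays lie above wild type for the first 7 genes and below for Atp5a1, though 0 of the 8 passed limma's threshold over all genes.

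Among published targets of the microRNAs in the title, those of miR-101 were higher in knock-in as a list. Of 14 members 9 were higher, with a mean of 0.26 and adjusted p = 0.0047 (adjusted p = 0.881 with an estimated correlation). Atxn1, which encodes an ataxin, differed by 0.63 (SE 0.15) on its brightest probe and by -0.38 on its other one, the phosphatase gene Dusp1 by 0.90, Ptgs2, which encodes an inducible cyclooxygenase, by 0.68 and Fos by 0.94. Fos and Dusp1 also belong to the activity-regulated list. Without these 2 members the mean of the other 12 was 0.15, with 7 of them higher. Camera then gave an unadjusted p of 0.0108, and 0.112 with an estimated correlation. The 12 still held Atxn1 and Ptgs2, and whether these or other members respond to neuronal firing was not tested. With slide as a block the list mean was 0.32 (adjusted p = 0.0015), and 3 members passed when adjusted over the list alone. Targets of miR-221 had a mean of 0.09 over 12 members (adjusted p = 0.137), with Ets1 at 0.42 on its brightest probe and -0.34 on its other one, and Timp3 at 0.30; with slide as a block the mean was 0.21 and passed (adjusted p = 0.0052). It passed under 5 of 22 alternatives. Leaving out one array moved it between 0.027 without wild-type replicate 3 and 0.16 without wild-type replicate 2. Targets of miR-129-5p had a mean of -0.10 over 6 members (-0.014 with slide as a block, and between -0.06 and -0.15 on leaving out one array), 4 of them lower, among them Atp2b4 at -0.48 and Kcna1 at -0.21. Genes of the microRNA pathway had a mean of -0.04, with the Argonaute gene Ago4 at 0.39 and Dgcr8 at -0.17.

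Lists tied to FMRP itself did not pass, and their means too are to be read against the median of -0.05 over all genes. FMRP relatives and partners had a mean of 0.02 over 14 members, with Ybx1 at 0.33, Cyfip2 at -0.18 and Cyfip1 at -0.13. Well-known FMRP target transcripts had a mean of -0.06 over 32 members, 20 of them lower. Leaving out one array moved that mean between -0.09 without wild-type replicate 1 and -0.0086 without wild-type replicate 2. Arc (1.16), Eif4g2 (0.65), Ube3a (0.39) and Gabrd (-0.35) had the smallest p. Eif4g2 read 1.78 in wild-type replicate 2, against 2.75 and 2.63 in wild-type replicates 1 and 3. Proteins that bind CGG-repeat RNA or occur in its inclusions had a mean of 0.04 over 19 members, among them Hspb1 at 0.63 (SE 0.35) and Vim at 0.35. Both genes overlapped between groups, and Hspb1 read 1.53, 0.76 and 0.18 in knock-in replicates 1 to 3. The chromosomal neighbours of Fmr1 had a mean of -0.10 over 18 members, 13 of them lower (adjusted p = 0.390), with Mtm1 at 0.31 and Ldoc1 at -0.26.

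Synaptic lists did not pass either, and their means are to be read against a median of -0.05 over all genes. Presynaptic vesicle and release genes had a mean of -0.10 over 36 members, 26 of them lower (adjusted p = 0.184), with Unc13a, which primes vesicles for release, at -0.48, Amph at -0.31 and Synj1 at -0.28; with slide as a block the mean was -0.17 and passed (adjusted p = 0.0088). It passed under 4 of 22 alternatives. Leaving out one array moved it between -0.048 without knock-in replicate 1 and -0.16 without knock-in replicate 3. Postsynaptic density genes went both ways around a mean of 0.00, with Arc at 1.16, Lrrc7 at 0.56, Homer1 at -0.44 on its brightest probe and Sipa1l1 at -0.26. Glutamate receptor genes had a mean of -0.06, with Grin2a at -0.57 (SE 0.27), Grm2 at -0.38 and Grin2d at 0.42. The mean lay between -0.09 without knock-in replicate 3 and -0.03 without wild-type replicate 2. Grin2a read 2.58 in wild-type replicate 2, against 1.74 and 1.58 in wild-type replicates 1 and 3. GABA synapse genes had a mean of -0.06, with the receptor genes Gabbr2 at -0.79 (SE 0.25) and Gabrd at -0.35, both wholly below wild type. Translation factors had a mean of -0.02, with Eif4ebp2 at 0.51, Eif3a at 0.42 and Eif4a2 at -0.28 on its brightest probe and 0.18 on its other one. Cytosolic ribosomal proteins had a mean of -0.09 over 78 members, 60 of them lower (adjusted p = 0.115). Their direction depended on the processing: of 22 alternatives 5 passed as lower, among them leaving out wild-type replicate 3 (-0.15, adjusted p = 0.0022) or knock-in replicate 2 (-0.13, adjusted p = 0.0036), and 1 as higher, the authors' value table (0.05, adjusted p = 0.0408). The mean turned to 0.04 with slide as a block (adjusted p = 0.0716).

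Markers of brain regions differed among arrays of both groups. Striatal markers, mostly genes of medium spiny neurons, had a mean of 0.86 higher in knock-in and passed (16 of 17 higher, adjusted p = 0.0175, and 0.918 with an estimated correlation), but 0 members separated the groups. Relative to the mean of all 6 arrays they read 1.83, 0.40 and -0.94 in knock-in replicates 1 to 3 and 1.33, -1.30 and -1.32 in wild-type replicates 1 to 3, an exact permutation p of 0.5 for the list mean. Six3, well above background on 1 of the 3 wild-type arrays, differed by 2.39 (SE 1.73), Syndig1l by 1.96 (SE 1.22), Gpr6 by 1.35 and Ppp1r1b by 0.58. Without knock-in replicate 1 the list mean was 0.16 and without wild-type replicate 2 or 3 it was 0.42 or 0.41, each short of the threshold, and 5 of 21 alternatives lost the call; with slide as a block it was 1.75 (adjusted p = 1.01e-04). Choroid plexus and ependymal markers followed the same arrays, at 0.75, 0.89 and -0.57 in knock-in and 0.95, -0.86 and -1.16 in wild type, with a mean difference of 0.71 (adjusted p = 0.0507). It passed under 9 of 22 alternatives, with slide as a block at 1.52, but fell to 0.17 (adjusted p = 0.617) with probes well above background on all arrays only. It lay between 0.31 without wild-type replicate 3 and 1.37 without wild-type replicate 1 on leaving out one array. Midbrain and hindbrain markers had a mean of 0.42 (adjusted p = 0.118). It was 0.10 without knock-in replicate 1. It passed under 3 of 22 alternatives: without knock-in replicate 3 (0.70, adjusted p = 0.0180), without wild-type replicate 1 (0.76, adjusted p = 0.0293) and with the replicate block (0.42, adjusted p = 0.0186). Among these markers was Tph2, the serotonin synthesis enzyme, well above background on 0 wild-type arrays and at least 1.55-fold higher. Cortical and hippocampal markers had a mean of -0.08, with Emx2 at 0.58 and Tbr1 at -0.41, and thalamic markers 0.08, with Calb2 at 0.39. Cerebellar markers had a mean of 0.02, with Car8 at 1.79 (SE 0.76). Car8 read -4.63 in wild-type replicate 2, against -1.70 and -2.09 in wild-type replicates 1 and 3. Hypothalamic and pituitary markers had a mean of -0.04, with Agrp at -0.57 and Hcrt at -0.48. None of these 4 lists passed, though the thalamic one did without a filter on dim probes (0.15, adjusted p = 0.0373).

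Among cell types, oligodendrocyte and myelin markers were higher in knock-in as a list: 16 of 20 were higher, with a mean of 0.20 and adjusted p = 0.0047 (adjusted p = 0.881 with an estimated correlation). Mobp differed by 0.50 (SE 0.18) and Mog by 0.33, and 0 members separated the groups; without wild-type replicate 2 the mean was 0.09 and missed the threshold, as it did with striatal markers as a covariate (0.097, adjusted p = 0.136), chosen after seeing the data. The mean was 0.26 with slide as a block (adjusted p = 0.0015). Red blood cell markers passed with 7 of 7 higher and a mean of 0.36 (adjusted p = 0.0101, and 0.881 with an estimated correlation), led by the haemoglobin gene Hba-a1 at 0.61. That call was lost with slide as a block (mean 0.32, SE between arrays 0.42 against 0.26 without the block, adjusted p = 0.0570), the mean fell to 0.13 without knock-in replicate 1, and 6 of 22 alternatives lost the call. Microglia markers passed narrowly, with 12 of 18 higher and a mean of 0.08 (adjusted p = 0.0463, and 0.881 with an estimated correlation); Fcrls differed by 0.28, C1qa by 0.32 and Cx3cr1 by -0.26 on its brightest probe and 0.47 on its other one. With slide as a block the mean was 0.15 (adjusted p = 0.0052), but 7 of 22 alternatives lost the call, among them leaving out knock-in replicate 1, where the mean stayed at 0.077 with fewer arrays (adjusted p = 0.130), knock-in replicate 2 (mean 0.06, adjusted p = 0.120) or wild-type replicate 3 (mean 0.05, adjusted p = 0.445) and the striatal covariate (mean 0.053, adjusted p = 0.220), chosen after seeing the data. Astrocyte markers had a mean of 0.02, with Gfap, the intermediate filament of reactive astrocytes, at 0.75 (SE 0.26) and wholly above wild type. Endothelial and mural markers had a mean of -0.04, which lay between -0.23 without knock-in replicate 1 and 0.10 without knock-in replicate 3, with Cldn5, a tight junction protein, at -0.99 (SE 0.30) and wholly below. Transcripts retained in neuronal somata and nuclei had a mean of -0.03, with Rbfox3 at -0.32. Of the sex-linked markers 2 were measured and not tested as a list, Ddx3y at 0.08 and Eif2s3y at -0.26. Both lie on chromosome Y and were well above background on all 6 arrays, so signal of Y-linked genes was found in every sample.

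**Figure D3:**
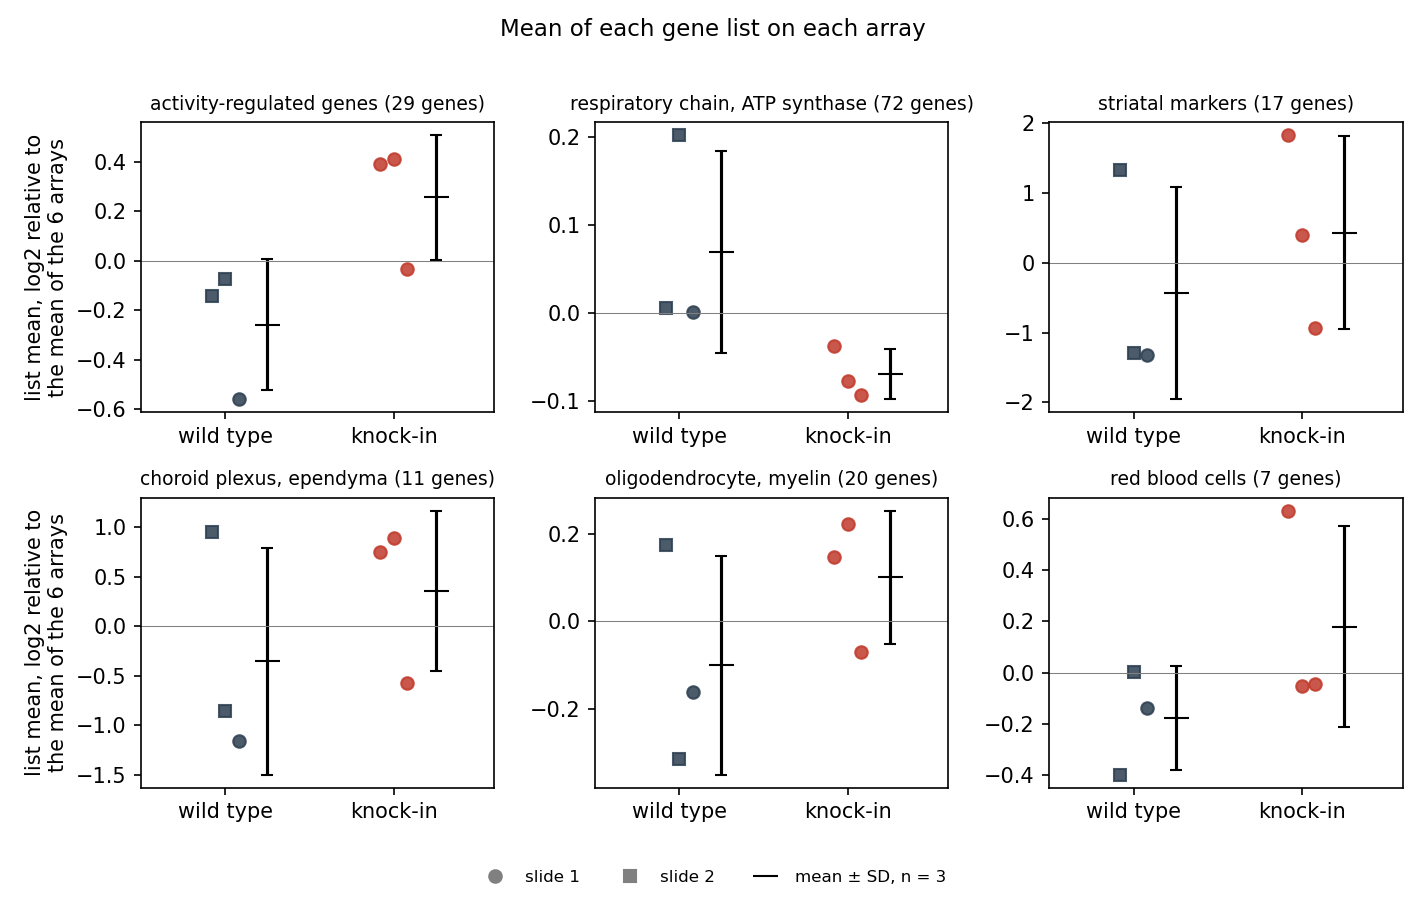
Mean of 6 gene lists on each array, log2 relative to the mean of the 6 arrays. Circles are slide 1, squares slide 2, and bars the mean ± SD (n = 3); striatal markers run from -1.32 to 1.83 with both groups at both ends, while for activity-regulated genes the 3 knock-in arrays lie above the wild-type ones.

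By the list tests, 8 of 30 lists passed with camera's preset correlation, 7 of them higher and 1 lower in knock-in. With an estimated correlation 0 passed, and by fry, which asks whether the members of a list move one way on balance, 0 passed. Of the 22 lists that did not pass, 8 had a mean whose sign turned on leaving out one array: cerebellar, hypothalamic and pituitary, cortical and hippocampal, and endothelial and mural markers, postsynaptic density, somatic and nuclear transcripts, the microRNA pathway and translation factors.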

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

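The Fmr1 difference kept its sign and stayed short of the threshold under all 22 alternatives, between 0.55 with the mean of all probes and 0.91 with knock-in and wild-type replicate 1 left out, with adjusted p between 0.0874 and 0.648. Leaving out those 2 arrays, and a striatal covariate, were chosen after seeing the data. The count of 2 genes stayed within 1.5 times under 8 alternatives and moved further under 15. It was 7 with slide as a fixed block, 5 on slide 1 alone, 5 with slide as a random block, 6 with an intensity trend and robust moderation, 5 with the mean of all probes of a gene and 1 with normexp. It was 0 without a filter on dim probes, with the stricter filter, with the authors' value table, without knock-in and wild-type replicate 1, and with the striatal covariate; in these limma fits 1511 to 3490 genes had an unadjusted p under 0.05. Leaving out one array at a time gave 0 to 3 genes, and 0 without wild-type replicate 1 or 2. Under the fixed slide block 0 of the 2 genes remained past the threshold, with differences of 3.47 and 4.39 against 3.51 and 4.23 and larger standard errors. The causes were not tested, except that fewer arrays or more terms leave fewer degrees of freedom.

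The labels do not say whether the replicate numbers pair the samples, and the values do not settle it. Deviations of same-numbered arrays correlated across genes between -0.02 and 0.40, and 4 of the 6 arrays correlated best with their own number. The SE between arrays of the activity-regulated list mean was 0.015 with the replicate block, against 0.21 without it. For striatal markers it was 0.42 against 1.19. With the replicate block 0 genes and 10 lists passed, with 2413 genes at an unadjusted p under 0.05.

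The count of 8 lists became 0 with camera's estimated correlation and 0 by fry, whose constructions allow for the correlation among members, and ranged from 5 to 11 on leaving out one array, with 5 without knock-in replicate 1. Over the 8 lists, 150 of 175 values kept their direction and call, 25 lost the call and 0 reversed. The activity-regulated and miR-101 lists were past the threshold under all 22 settings run with the preset correlation. The striatal list has no value with its own mean as covariate. Among the single genes named, 424 of 455 values kept direction and side, 5 newly passed (Sult2a7 under 4 alternatives and Mcts1 under 1), 25 lost a call, all of them values of the only 2 called genes, whose calls were lost under 13 and 12 of 21 alternatives, and 1 reversed, Itgax at -0.076 with normexp. Signal over background limits genes such as Sult2a7, Tcim and Atad3aos, whose folds are bounds. The comparison of microRNA seed matches, with its 2 alternatives, was not run.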

Other observations

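The slide tests, the probe test for Fmr1, the comparison of the glucocorticoid and activity-regulated lists array by array and the chromosome counts were chosen only after the results were seen; the lists of clock, glucocorticoid and further endoplasmic reticulum genes were written after the patterns were seen and before their own values were. Members of those lists are named here after their values were seen.

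Manf and Pdia4, folding proteins of the endoplasmic reticulum that were singled out after their values were seen, differed by 0.55 (SE 0.09) and 0.67 (SE 0.11). Among 25 further targets of the unfolded protein response, 18 were higher, and 8 lay wholly above wild type. Of these, Sdf2l1 was at 0.67, Edem1 at 0.66, Txndc5 at 0.64, Creld2 at 0.55 and Dnajb11 at 0.35. Hyou1 (-0.02) overlapped and Canx (-0.13) was the 1 wholly below. The targets left out of these 25 as already seen include Crebrf, at -0.36 with overlap. Over all 32 targets, 24 were higher, with a mean of 0.21. Glucocorticoid-responsive genes had a mean difference of 0.29 over 15 members, 12 of them higher, with Plin4 at 0.83, Pdk4 at 0.60, Sgk1 at 0.57, Tsc22d3 at 0.49 and Fkbp5 at 0.38 and 6 members wholly above wild type. Clock genes went both ways: Per2 differed by 0.88, Ciart by 0.73 and Clock by 0.37, and Per3 by -0.68 and Hlf by -0.33. None of these genes passed limma's threshold over all genes.

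The activity-regulated genes were higher in knock-in by 0.51. Slide cannot be told apart: with slide as a block the list mean was 0.81 (95% interval 0.05 to 1.58), but that fit rests on the 1 wild-type array of slide 1. The share of striatal tissue stays open too. With striatal markers as a covariate the difference was 0.42 (SE 0.21), above the bound set beforehand, and the camera call was kept. It lay above that bound by less than its SE, a margin that the rule set beforehand did not ask for. Time of day also stays open, because the clock score differed by 0.11 with an SE of 0.12 and its members opposed each other. A glucocorticoid response at collection is not decided either. Its list was higher by 0.29 (SE 0.10, unadjusted camera p = 6.44e-06, and unadjusted p = 0.0379 with an estimated correlation). The activity-regulated list had an unadjusted camera p of 0.104 with an estimated correlation. Within groups, however, the array means of the 2 lists had a correlation of 0.0338. The glucocorticoid means were 0.01, 0.28 and 0.16 in knock-in replicates 1 to 3 and -0.25, -0.05 and -0.14 in the wild-type ones. Genotype remains open beside these.

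The Fmr1 difference was found on all 3 of its probes. A sequence difference under 1 probe is argued against as the whole cause, since it would move that probe only, and 3 of 3 probes separated the groups; the extra 0.40 of the brightest probe and sequence differences under several probes were not tested. Slide cannot be told apart: with slide as a block the difference was 0.83 (95% interval 0.49 to 1.16), where a slide effect alone would give 0, but the fit rests on the 1 wild-type array of slide 1. A higher Fmr1 transcript level in knock-in stays open beside it.

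The endoplasmic reticulum chaperones Hspa5, Manf and Pdia4 were higher on all 3 knock-in arrays. Slide cannot be told apart: with slide as a block their mean difference was 0.51 (95% interval 0.35 to 0.67), but the fit rests on the 1 wild-type array of slide 1 and on 3 genes chosen for their difference. A wider stress response of that organelle predicts that members not yet looked at are higher too. By camera with an estimated correlation, the planned heat shock list had an unadjusted p of 0.0689. The 25 further targets had a mean of 0.18 (SE 0.04, unadjusted camera p = 1.57e-05, and unadjusted p = 0.0086 with an estimated correlation). That is consistent with a shared response, as a hypothesis from the same 6 arrays; whether it follows genotype or handling of the tissue was not tested.

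The 6 arrays make 10 splits into 3 and 3, too few for a share under 0.05. The real split called 2 genes and the highest of the others 2, and 3 of the 10 splits called as many as the real one. For the gene lists the real split put 8 past the threshold and the highest of the others 9, and 2 of the 10 splits reached the real count. The split with 9 lists sets knock-in replicates 1 and 2 and wild-type replicate 1, the 3 arrays with the highest striatal markers, against the rest, and it has 2330 genes at an unadjusted p under 0.05 against 2276 for the real one. The mean of the activity-regulated list differed by 0.51 in the real split and by 0.44 in this one. It differed by 0.49 with knock-in replicates 1 and 2 and wild-type replicate 2 set against the rest.

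The genes of smallest p were not gathered on one chromosome. Among the 100 genes of smallest p, 99 were placed; chromosome 4 held 11 where 6.16 were expected (Fisher's exact p = 0.0566, adjusted p = 0.566), and chromosome X held 4 where 3.77 were expected. Of these genes 8 lay within 1 Mb of another, and 897 of 1000 random draws had as many. Atad3aos and Aurkaip1, both lower in knock-in, lie 70.8 kb apart on chromosome 4.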
